A study of Mus musculus with 4 samples.

How the data were processed

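Total RNA of thymus and brain from adult C57BL/6J mice, an inbred laboratory strain, was measured on 2-colour Agilent oligonucleotide arrays. Per the labels, the RNA was extracted with Trizol and labelled with Cy3 or Cy5 after low-input linear amplification. Each tissue has 2 samples, which the labels call biological replicates without naming the animals. Replicate 1 of each tissue carried Cy3 and replicate 2 carried Cy5, per the labels, so replicate number and dye are the same factor. The deposited readme states that the other channel of each array held a universal mouse reference RNA, a pool made from mouse cell lines and used here as the same material on all 4 arrays.

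The spot intensity values were made by the authors with Agilent Feature Extraction 10.5.1.1, per the submitters' processing notes and the file headers. Per the file headers, this software subtracted the local background, removed spatial trends and normalized the dyes against each other within each array, with a linear and a lowess step, to give the processed signal. It did not scale the arrays to each other. The deposited log10 ratio of each spot is that of the red over the green processed signal, per the file headers. The authors' deposited value table holds log2 values. Each of its columns differed from the log2 processed signal of the sample's own channel by a constant, to within 0.001 for 99.99% of probes in every sample. It is therefore a single-channel measure centred per array, and not a ratio to the reference. Its column medians were 0, 0.004, -0.0013 and 0.0047 for thymus 1, thymus 2, brain 1 and brain 2. Its direction is thus known, and the centring constant is not given in the sources used here.

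The design was written before the data were examined and was kept although the arrays turned out to have 2 colours. Values were log2 of the processed signal in the channel whose dye the labels give for the sample. The sample's 75th percentile over non-control probes was then subtracted, so that 0 stands for the 75th percentile of that sample. Each array has 44290 spots, of which 42034 are not controls, for 41821 probes under 41819 systematic names. Spots of a probe were averaged after control spots and spots flagged as outliers had been left out. A probe was kept when the scanner software called it well above background in both samples of at least 1 tissue. This kept 27275 probes, of which 126 had no value in some sample because of outlier flags. For the 2 systematic names with several probes, the probe with the highest mean was used. The test covered 27147 features.

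Brain and thymus were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no covariate), with Benjamini-Hochberg adjustment and a threshold of 0.05. The fit had 2 residual degrees of freedom per feature and 4.97 prior degrees of freedom, so each test leans on the spread pooled over features. Each tissue holds one sample of each dye, so a dye effect alike in both tissues cancels in the difference. Adjusted p-values below are all from limma. The p-values rest on the spread between these samples. Within a tissue the samples also differ in dye, so this spread holds dye and sample differences together. The small number of arrays limits the precision of every value.

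The analysis was tested on simulated data drawn at the spread of the brain minus thymus comparison, over 27147 features. With 200 features changed, 0, 1, 17 and 31 of 50 were recovered at log2 changes of 1, 2, 3 and 4, with 1 false call. With 2222, 2359, 2227 and 2241 features changed by those sizes, 61.3%, 91.4%, 96.3% and 98.5% were recovered, and 3.51% of the calls were false. Where few features change, even a log2 change of 4 in 1 feature can therefore be missed at this sample size. The spreads were shuffled over features, so the simulation does not keep any link between dim signal and spread. Each spread was the residual SD of a feature on 2 degrees of freedom, taken as if known. Errors were drawn independently, without a dye component shared by the tissues. The recovered shares are therefore approximate.

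The array is a custom design whose probes mostly carry project or clone identifiers. Of 41821 probes, 124 are named by a GenBank or RefSeq accession and 14 of these start with NM. A table of RefSeq genes of the assembly GRCm38.p6 gave a gene symbol for 13 of the 14, and the rest of the array, 41808 probes, stayed unnamed here. The files name no genome build, so no coordinates are given. The rule for named genes, fixed before the data were examined, took the genes with the largest folds in each direction, the largest bounds, the leading members of 33 marker and pathway lists, and any member of the germ cell, pluripotency, DNA methylation, repressive chromatin and X or Y lists. With so few symbols, it was widened after the files were seen to all 13 genes with a symbol, whatever their values. For the unnamed probes, the 2 identifiers with the largest fold in each direction are given among features past the threshold, well above background in all 4 samples, not saturated and with no overlap between the tissues. Of the 33 lists, 3 had at least 1 measured member and none had more than 2, so no list test was run.

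A fold was read as a lower bound where a feature was not well above background in either sample of the lower tissue. The lower tissue then took, per sample, the higher of its own signal and the lowest signal of any probe well above background. Alternatives fixed before the data were examined covered the scaling, the background correction, the filter on dim probes, the replicate block, the prior, a fold threshold, the authors' values, the probe per name, saturated probes and each sample left out. Alternatives added afterwards were the ratio to the reference RNA, a common detection floor, normexp on median signals because the files used here give no mean spot signals, each sample left out with the tested features held fixed, and scan day as a random block. Both thymus arrays were scanned on the same day and each brain array on a day of its own, per the file headers, and the 4 arrays are on 4 slides. No scan day holds both tissues.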

Results

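The arrays measured RNA abundance in whole thymus, the organ in which T cells mature, and in brain, with 2 samples of each. They belong to a study of DNA methylation in primordial germ cells, whose own data are not analysed here. The question open to these 4 samples is which transcripts differ between brain and thymus. The share of probes well above background was 60.4% in thymus 1, 97.3% in thymus 2, 55.7% in brain 1 and 84.2% in brain 2. The Cy5-labelled sample of each tissue thus had the larger share. Among 314 negative-control spots, 1.27%, 1.59%, 1.91% and 3.5% were called well above background in the same order of samples. Median processed signals were 365.2, 552.9, 338.8 and 405 intensity units. Saturated probes numbered 286 in thymus 1, 499 in thymus 2, 50 in brain 1 and 220 in brain 2.

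Samples of the same tissue were much closer to each other than samples of different tissues. Across the 27147 tested features, which are not independent replicates, Pearson's r was 0.962 between the brain samples and 0.971 between the thymus samples. Spearman's rho was 0.957 and 0.974. Between tissues, r ran from 0.698 to 0.738. The replicate difference had an SD of 0.574 log2 units in brain and 0.507 in thymus, and 93% and 94.3% of features lay within 2-fold between replicates. These differences include the dye as well as the sample. The replicate differences of the tissues, each between dyes, correlated at 0.257 across features. Without the filter on dim probes, the thymus SD rose to 0.799, and with normexp and quantile normalization it was 0.323.

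Brain and thymus differed widely. The adjusted p was under the threshold for 8989 of 27147 features (33.1%), of which 4411 were higher in brain and 4578 higher in thymus. Without adjustment, 5317 and 5955 features had p under 0.05. The largest differences were more often towards brain. At 8-fold or more there were 1148 features higher in brain and 596 higher in thymus, and at 32-fold or more there were 296 and 106. These counts depend on dim signals and on the background correction. Among features well above background in all 4 samples they were 447 and 212 at 8-fold and 81 and 18 at 32-fold, and with normexp and loess ratios to the reference 496 and 201, and 47 and 14. The median fold was 3.96 for features higher in brain and 2.97 for those higher in thymus. Among called features well above background in all 4 samples, 2884 were higher in brain and 3027 in thymus, with median folds of 3.15 and 2.7. In 1493 called features higher in brain and 1338 higher in thymus, only 1 sample of the lower tissue was well above background. The size of these folds is uncertain. In a further 34 features higher in brain and 213 higher in thymus, neither sample of the lower tissue was well above background. Their folds are lower bounds, with medians of at least 12-fold and at least 3.43-fold. The bounds use each sample's lowest signal well above background. In scaled log2 units it was -2.77 in thymus 1, -6.72 in thymus 2, -2.42 in brain 1 and -4.88 in brain 2. The floor thus differs between the directions, and the medians are not directly comparable. Signals of both samples of a tissue did not overlap those of the other in 17666 features (65.1%), where chance gives 33.3%. The median difference over all tested features was -0.11 log2 units, brain minus thymus. The counts depended on single samples. Without thymus 1 the number of calls was 2388, and without brain 1 it was 3364. In these fits one tissue rests on its Cy5 sample alone. A feature's spread then comes from the 2 samples of the other tissue and from the pooled prior, and the lone sample is assumed to vary likewise. In some fits with a sample left out the pooled spread alone was used. Each tested gene with a symbol had the same SE without thymus 2, at 0.499. The same held without thymus 1 with the tested features held fixed, at 0.498. As the Cy5 samples have more probes well above background, the background filter let in more dim features. With the tested features held fixed, the counts were 6602 without thymus 1 and 8076 without brain 1. Without the filter on dim probes 5007 features were called, and against a log2 difference of 1 there were 3535.

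**Figure D1:**
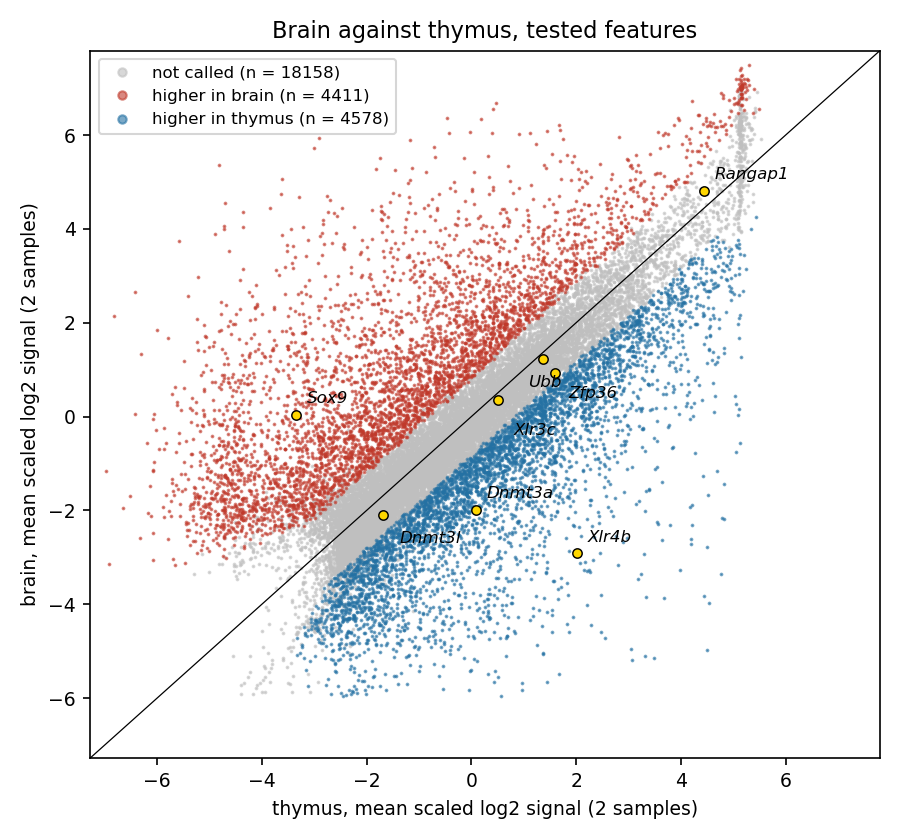
Mean scaled log2 signal of brain (vertical axis) against thymus (horizontal axis) for the 27147 tested features, 2 samples per tissue, where 0 is the 75th percentile of a sample. Red points are the 4411 features higher in brain, blue points the 4578 higher in thymus, grey points the 18158 not called, and gold circles the 8 tested genes with a symbol. The narrow column of points near the right edge holds features saturated in thymus, where 286 tested features were saturated in both samples.

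Of the genes with a symbol, 8 could be tested and 3 passed the threshold, both over all features and when adjusted over the list alone, that is over these 8. Xlr4b, a member of the X-linked lymphocyte-regulated family, was higher in thymus, at 2.02 ± 0.22 scaled log2 units (SD, n = 2) against -2.92 ± 0.07 in brain. The difference, brain minus thymus, was -4.93 (SE 0.26), or 30.5-fold in size, with a limma adjusted p of 4.8e-05. Only 1 of the 2 brain samples was well above background at this probe, and the size of the fold is uncertain. Over the alternatives the difference ran from -5.09 to -3.81, with the smallest size in the normexp and loess ratio to the reference. Near-identical members of the family may share its signal, so the assignment to Xlr4b is uncertain. Dnmt3a, a DNA methyltransferase that sets new methylation marks, was also higher in thymus, at 0.08 ± 0.08 (SD, n = 2) against -1.99 ± 0.07 in brain. Its difference was -2.07 (SE 0.25), or 4.19-fold, with a limma adjusted p of 0.000892, and all 4 samples were well above background. Without thymus 1 the Dnmt3a difference was -2.01, and Dnmt3a did not pass the threshold. With the tested features held fixed the difference was the same. That fit gave each tested gene with a symbol the same SE, 0.498, so it used no spread of Dnmt3a's own. Over all alternatives the adjusted p of Dnmt3a ran from 8.67e-06 to 0.0777 and the difference from -2.13 to -1.30, the latter with the normexp and loess ratio. Sox9, a transcription factor of neural progenitors, astrocytes and cartilage, was higher in brain, at 0.04 ± 0.13 (SD, n = 2) against -3.35 ± 0.85 in thymus. Its difference was 3.39 (SE 0.41), with a limma adjusted p of 0.000867, and 1 of the 2 thymus samples was well above background. The Sox9 difference was 2.79 without thymus 1, 3.99 without thymus 2 and 2.11 with the normexp and loess ratio, the lowest of the alternatives. Signals of each of these 3 genes did not overlap between tissues.

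The other 5 tested genes did not pass the threshold. Zfp36, which encodes an RNA-binding protein that promotes mRNA decay, had a brain minus thymus difference of -0.66 (SE 0.26, limma adjusted p 0.103). For Dnmt3l, a cofactor of the methyltransferases without catalytic activity of its own, the difference was -0.41 (SE 0.29, limma adjusted p 0.346). The SD between brain samples was 0.38 for Dnmt3l, and its difference was -0.14 without brain 1, -0.68 without brain 2 and -0.10 with normexp. Rangap1, the GTPase-activating protein of Ran, differed by 0.37 (SE 0.25, limma adjusted p 0.324). Xlr3c, of the same family as Xlr4b and with the same uncertainty, differed by -0.16 (SE 0.25, limma adjusted p 0.708). Ubb, a polyubiquitin gene, differed by -0.15 (SE 0.28, limma adjusted p 0.745), and the sign turned to 0.067 without brain 1. Zfp36 passed the threshold in 4 alternatives, with adjusted p from 0.0167 to 0.0415, and over all alternatives its adjusted p ran from 0.0167 to 1.

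**Figure D2:**
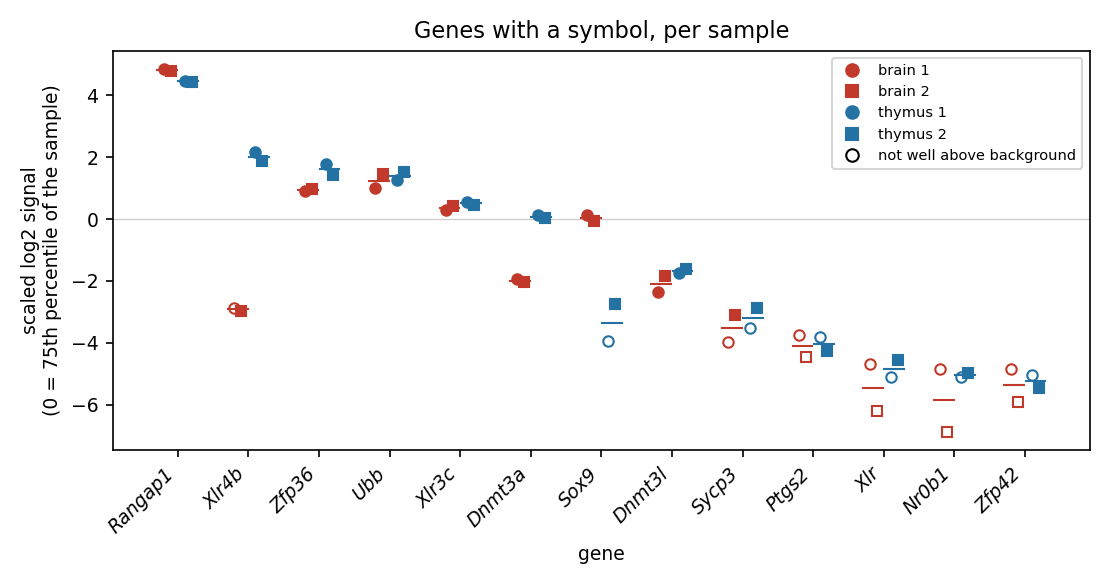
Scaled log2 signal (vertical axis, 0 is the 75th percentile of a sample) of the 13 genes with a symbol, one point per sample, with red for brain, blue for thymus, circles for replicate 1 and squares for replicate 2. Short lines are means of 2 samples and open symbols mark samples not well above background. Xlr4b and Dnmt3a lie higher in thymus and Sox9 higher in brain, with brain minus thymus differences of -4.93, -2.07 and 3.39 log2 units.

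The remaining 5 genes with a symbol were not well above background in both samples of either tissue and were not tested. They were Sycp3, a protein of the synaptonemal complex of meiosis, Zfp42, a marker of pluripotent cells, Nr0b1, a nuclear receptor of steroidogenic tissue and embryonic stem cells, Ptgs2, the inducible cyclooxygenase, and Xlr. Each was well above background in thymus 2, the sample in which 97.3% of probes were, and Sycp3 also in brain 2. Of the germ cell list, Sycp3 was the 1 member measured, of the pluripotency list Zfp42, and of the DNA methylation list Dnmt3a and Dnmt3l. In the last list 1 of 2 members was higher in thymus and 1 did not pass the threshold.

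Among the unnamed probes, TF39959 had a signal of 5.50 ± 0.43 in brain (SD, n = 2) and -1.74 ± 0.10 in thymus, a difference of 7.25 (SE 0.30) or 152-fold. TF14526 differed by 7.10 (SE 0.26) or 137-fold. Towards thymus, TB1209 differed by -6.54 (SE 0.25), 93-fold in size, and TB1205 by -6.18 (SE 0.25), 72.7-fold in size. The limma adjusted p was 3.17e-05 for each of these 4, the smallest of the comparison. They were taken for the size of this difference, and as ratios to the reference RNA, an alternative added afterwards, each was smaller. By the scanner software's ratio TF39959 differed by 4.91, TF14526 by 6.14, TB1209 by -5.05 and TB1205 by -3.71, and with normexp and loess by 4.64, 5.74, -4.34 and -3.53, so that TF14526 was then the larger of the pair towards brain. The files used here do not pair these identifiers with gene names.

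Transcripts detected in 1 tissue alone were few by the scanner's own calls. By systematic name, 23172 (55.4%) were well above background in both brain samples and 25235 (60.3%) in both thymus samples, with 21134 in both tissues. Only 35 were detected in brain and in neither thymus sample, and 292 in thymus and in neither brain sample. These counts depended on the sample and on the rule. Without thymus 2 there were 2038 in brain alone, without brain 1 there were 106, without brain 2 there were 4088 in thymus alone, and without thymus 1 there were 5506. With 1 floor for all samples, at a scaled log2 signal of -2.16, 1564 were detected in brain alone and 1357 in thymus alone.

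The reference RNA on the same arrays gave a measure of differences between arrays. Its signal correlated at 0.966 to 0.975 across features between arrays. Brain arrays against thymus arrays gave 0 calls in the reference channel with limma, and 1055 features (3.88%) at an unadjusted p under 0.05. The SD of the difference was 0.366 log2 units in the reference and 1.49 in the tissue RNA. For Xlr4b, Dnmt3a and Sox9 the reference differed by 0.06, -0.24 and -0.02 log2 units. Relative to the reference on each array, Xlr4b was -3.90 in brain (limma adjusted p 4.35e-05) and 1.08 in thymus (0.00357). Dnmt3a was -0.16 in brain (0.534) and 1.65 in thymus (0.0028), and Sox9 was 2.17 in brain (0.00419) and -1.25 in thymus (0.0502).

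**Figure D3:**
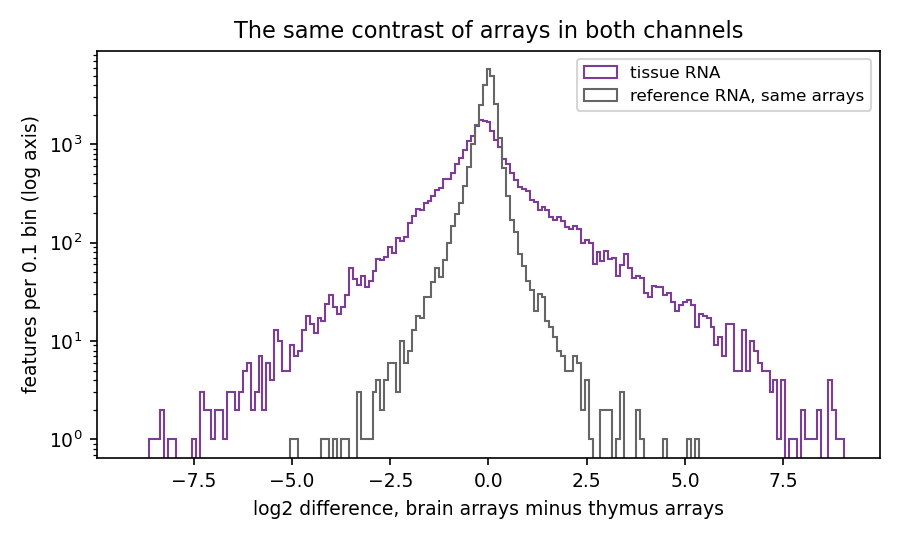
Number of features per bin of 0.1 log2 units (vertical, log axis) against the difference of brain arrays minus thymus arrays (horizontal axis), for tissue RNA and for the reference RNA on the same 4 arrays. The SD is 1.49 for tissue RNA and 0.366 for the reference.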

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

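At 494 probes the reference RNA was well above background on all 4 arrays while neither tissue was well above background in both of its samples. This signal lies in the channel that the comparison of tissues does not use. The 494, which include the probes of Ptgs2 and Xlr, are part of 23097 probes at which the reference was well above background on all 4 arrays. At 3 of the 494, no tissue sample was well above background.

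Of the 5 genes with a symbol that were not tested, 2, Ptgs2 and Xlr, gave reference signal well above background on all 4 arrays, and Sycp3, Zfp42 and Nr0b1 gave it on none. The probes of Ptgs2 and Xlr thus gave signal on these arrays, which argues against silent probes for these 2 genes. For Zfp42 and Nr0b1, well above background only in thymus 2, a probe that gives no signal and RNA that is scarce in the tissues cannot be told apart. The Sycp3 probe was well above background in thymus 2 and brain 2, at scaled log2 signals of -2.86 and -3.09. The negative-control medians there were -8.88 and -6.72. This probe thus gave signal in these samples, and whether it came from Sycp3 RNA was not tested. Over the 5 genes as a set the question stayed open, since 2 of 5 is neither none nor most of them. No biological explanation was tested.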

How the results depend on the processing

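The ratio to the reference, the common floor and fits with the tested features held fixed were chosen after seeing the data. With all samples, calls fell by over 1.5 times with no filter on dim probes (5007, with 2769 higher in brain and 2238 in thymus; more features tested) and against a log2 difference of 1 (3535, with 2079 and 1456; a stricter test). Leaving out each sample gave 2388 to 9004 calls, 1523 to 4513 higher in brain and 865 to 4491 higher in thymus, lowest without thymus 1; a lone sample is assumed to vary like the other tissue. Calls ranged from 6976 to 11553 in the other alternatives with all samples. With the replicate block, which is also the dye, 10229 were called, including 8951 of the 8989. The labels do not say that a number marks a shared animal. Of the 8 tested genes, Xlr4b and Sox9 kept their calls in all alternatives that tested them, and the block changed no call among them. Dnmt3a lost its call without thymus 1 (more features tested), and with samples left out Ubb ran from -0.375 to 0.067, turning without brain 1 and with the tested features fixed too. Zfp36 gained a call in 4 alternatives; the cause was not tested.

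Detection in brain alone was 8 with the positive-and-significant flag, 119 with at least 1 sample, 1564 with the common floor and 35 to 2038 with samples left out. In thymus alone it was 5520, 1357 and 305 to 5506 for the last 3. These counts follow the flag, since the Cy5 samples had more probes well above background. The SD between thymus samples was 0.323 with normexp and quantile normalization and 0.799 with no filter (more dim features). The cause of the first was not tested. The median brain minus thymus difference moved from -0.11 to 0.018 with normexp and 0.017 with the loess ratio. Scan day as a fixed block was not run, as no day holds both tissues, and as a random block its correlation could not be estimated from 4 arrays. List tests and counts of receptor families were not run for want of gene names. Low signal over background limits features near the floor.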

Other observations

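The ratios to the reference, the counts by fold size under the alternatives, the dye test from samples of the same dye and the comparison of accession-named probes were chosen after results had been seen, and the tests of the reference channel against the tissue after their correlation was seen. Compared with the cell-line reference, brain was called different more often than thymus, both among features higher in brain and among those higher in thymus. Of 4618 features called higher in brain by the ratio to the reference, brain was called above the reference, at the same threshold, in 3753 (81.3%) and thymus was called below it in 1398 (30.3%). Of 4742 called higher in thymus, thymus was called above the reference in 1902 (40.1%) and brain was called below it in 3414 (72%). The median of brain minus reference was 1.5 log2 units in the first set, where the median of thymus minus reference was -0.17. In the second set the medians were -1.03 for brain and 0.4 for thymus. With normexp and loess the shares called were 78.6% and 36.7% in the first set and 51.4% and 67.6% in the second, and the medians were nearer 0, at 0.9 for brain and -0.13 for thymus in the first set and -0.61 and 0.35 in the second. With each sample left out in turn, on the same sets, the thymus median of the second set ran from 0.36 to 0.44. The sets were chosen on brain minus thymus, so the shares rest on which features were called. No difference in these shares between the sets or the tissues was tested across samples. Over all 27123 features, brain was called higher than the reference in 5890 and lower in 6165, and thymus in 3554 and 3462. The larger shares for brain are thus not particular to the called sets. Neither set could be read for cell types, since the features carry no gene names here.

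The excess of large differences towards brain held in each alternative run. At 8-fold or more there were 1007 against 612 without brain 1 and 803 against 303 with normexp. Saturation in thymus lowers its highest signals, and the lower limit of measurable signal differed between samples. Neither was corrected for in the main fit. With saturated probes left out, the counts were 1133 against 577 at 8-fold and 286 against 99 at 32-fold. Among features well above background in all 4 samples they were 447 against 212 at 8-fold. The excess was thus also present without the saturated or the dim features. Leaving saturated probes out does not show what their folds would be.

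The 8989 calls between tissues were set against array, dye and chance explanations. Array, hybridisation or scan differences common to both channels and wide enough to give these calls would show in the reference. It gave 0 calls with limma (1055 features at an unadjusted p under 0.05), which argues against them as the source of the calls as a whole. In the simulation with 200 features changed, 1 of 50 was recovered at a log2 change of 2. Array effects at some features could therefore be missed. A dye difference would be absent between samples of the same dye, yet the brain minus thymus differences of the Cy3 pair and of the Cy5 pair correlated at 0.915 across features, and 79.7% had the same sign. A split of the samples by dye gave 0 calls, which says little because the tissue difference then inflates the spread. The 3 splits of 4 samples are too few for a share under 0.05: 1 split, the real one, gave 8989 calls, and the highest of the others gave 0. The other splits each mix the tissues within a group, so their 0 calls say little for the same reason. The reference does not cover the steps before hybridisation, for which the sources used here name no batch. The difference of tissue, which the design names, is what the calls measure in these samples. It was not separated by a test from differences in those earlier steps.

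The reference channel was not wholly independent of the tissue on its array. Across 27125 features the brain minus thymus difference in tissue RNA and that in the reference correlated at 0.394, with a slope of 0.0962. Dye normalization between the channels is argued against as the whole source, since the slope before it was 0.836 of that after. Effects of the spot or array shared by both channels could not be settled, as the covariance in the split that crosses tissue and dye was 24.8% of that in the split by tissue. The covariances were 0.0532 in the crossed split and 0.214 in the split by tissue. In the split by dye, which holds dye differences as well, the covariance was 0.0987. Tissue signal reaching the reference channel would weigh most where the reference is dim. The slope was 3.59 times as large in the dimmest as in the brightest of 3 equal groups of features, so such signal may account for part of the pattern. An additive spot effect shared by both channels would also weigh most there, so this slope does not tell these explanations apart.

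Detection of probes named by an accession was compared with that of the others in 3 tests, none of which gave a p under 0.05. Above the common floor in both samples lay 50% of 124 accession-named probes and 50.4% of the other 41697 in brain (Fisher's exact test p 0.929), and 52.4% and 51.3% in thymus (p 0.857). The reference RNA was well above background on all 4 arrays at 62.1% and 55.2% (p 0.125). After Benjamini-Hochberg adjustment over the 3 tests, p was 0.929, 0.929 and 0.376. In the reference channel, 57.4%, 86.1%, 68.7% and 61.1% of probes were well above background on the arrays of thymus 1, thymus 2, brain 1 and brain 2.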
